A study of Mus musculus with 4 samples.

How the data were processed

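The series holds RNA sequencing of whole mouse testis, the organ that contains the germ cells at every stage of spermatogenesis together with Sertoli, Leydig, peritubular, vascular and immune cells. Its labels describe 4 libraries, all from male C57BL/6J mice given LPS (lipopolysaccharide, a bacterial cell wall component that activates innate immunity), with 2 libraries of a Spry1 knockdown and 2 of a control hairpin. Per the labels' protocols, total RNA was extracted with TRIzol and made into libraries with a stranded mRNA kit. The labels do not say whether the replicates came from separate animals, so the p-values measure only the spread between these samples, which may be technical.

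The deposited values are raw read counts per gene in a single table of 49492 gene rows, whose leading columns (gene, chromosome, exon starts and ends, strand and length) are those of a featureCounts table. Per the submitters' processing notes, the authors used Trimmomatic 0.36, STAR 2.5.3a, featureCounts, Subread 1.5.1, edgeR 3.12.1 and DESeq, with genome build mm10. The notes give these names without roles or order. The annotation release, the strand setting of the counting and any use of molecular identifiers are not given in the sources used here. Without the strand setting, reads of overlapping genes, including antisense genes, cannot be assigned to either gene with certainty, and genes with near-identical copies are uncertain in the same way. Of the gene rows, 91.0% had the coordinates of a gene in GENCODE mouse release 21, which was used for gene types and for overlaps, and 86.8% had both its coordinates and its symbol. Of the deposited symbols, 26 had been turned into dates, and 25 of these were named again by position.

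The 4 count columns are headed LPS and NC, each with a number, and these headings are not the labels' sample titles. NC was read as the control hairpin and the remaining LPS heading as the Spry1 knockdown, with the number read as the replicate number. This assignment is a reading of the names and not an exact match, because LPS is part of all 4 titles. The counts of Spry1, of several inflammatory genes and of some other genes had been seen when it was written down, so the level of Spry1 is no independent check of it. If the headings instead stand for LPS against no LPS, the contrast is another one, and nothing in the sources used here settles this. The groups are therefore called the LPS columns and the NC columns throughout, and a positive log2 fold change means higher in the LPS columns.

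Total counts were 19187627 and 17612342 in LPS replicates 1 and 2, and 22451132 and 21081589 in NC replicates 1 and 2. A count of 0 in 1 library allows a level of up to 0.156, 0.170, 0.134 and 0.142 CPM (counts scaled to the library total) respectively, taking 3 counts as the floor. Replicates were compared by a chi-square test of their counts over genes, which gave a chi-square of 2.31 per degree of freedom for the LPS pair and 2.20 for the NC pair. Both pairs thus differed by more than sampling noise and were kept as separate samples, which does not show that they came from separate animals.

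Genes were filtered with filterByExpr of edgeR 4.0.16, counts were scaled by TMM factors, and the groups were compared with edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. A gene was called at an adjusted p under 0.05. The fit had 2 residual and 34 prior degrees of freedom, so the spread of a gene was estimated mainly from other genes. The standard error (SE) of a log2 fold change is the one implied by the quasi-likelihood F statistic. Apart from the floors of single libraries given above, CPM values use the TMM-scaled library sizes. For a gene at 0 in both libraries of a group, the fold is a lower bound against a floor of 3 counts over the group. For a group with 1 to 3 counts in total, the ratio of scaled counts is given with an exact binomial 95% interval. Intervals and floors cover counting error only.

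The tests, the gene lists, the named genes rule and the first set of alternatives were fixed before the data were examined, and the assignment of the columns to groups was made after some counts had been seen. The 26 lists cover NF-kB pathway and feedback genes, inflammatory cytokines, chemokines, LPS sensing and TLR4 signalling, interferon-stimulated genes, acute-phase and endotoxin-response genes, complement, MHC antigen presentation, ERK-responsive and RTK feedback genes, blood-testis barrier junctions, steroidogenesis and Leydig cell markers, Sertoli cell markers, peritubular myoid and smooth muscle markers, fibroblast and extracellular matrix genes, endothelial cell markers, macrophage and monocyte markers, neutrophil markers, lymphocyte and NK cell markers, erythroid genes, spermatogonia markers, meiotic spermatocyte markers, round spermatid markers, elongating spermatid markers, epididymis markers, apoptosis genes, and heat-shock and unfolded protein response genes. The 25 lists with at least 5 tested members were tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and fry were run beside it. With an estimated correlation camera takes its p from the 2 residual degrees of freedom of the fit. A list can hardly pass there after adjustment, whatever its correlation, so a failure there says little about a list. Where the estimate lies well above the preset, the p with the preset may be too small.

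The genes named are a fixed set (Spry1, Dmrt1, Tnf, Il1b, Il6, Ccl2, Cxcl10 and Nfkbia), the 10 genes with the largest change in each direction, and from each list up to 3 members with the smallest p. Genes with the largest change had to be called, to have a mean of at least 1 CPM, and to have both libraries of a group above both of the other, and unnamed gene models and pseudogenes by symbol were left out. Other genes are named where they complete a small count, are singled out beside a list or belong to a pattern of the closing section, and these were chosen after their values were seen. Some genes are not reported here.

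The procedure was tested on simulated counts drawn from the means and library sizes of these samples, with 200 changed genes. For this contrast it recovered 70.2% of genes changed 1.5-fold, 89.6% of those changed 2-fold and 100% of those changed 4-fold. It tested 20542 genes, and 2.81% of its calls were false. The changed genes were taken only from genes above a minimum mean count, so the recovery does not cover genes of few counts. Each gene was given the spread of the trend at its level, with none of its own. Far fewer genes were changed than were called in the data, so scaling under widespread change was not tested. The alternatives were other scalings (RLE, upper-quartile, library size only), no filter and a stricter filter on low counts, DESeq2 1.42.0, edgeR's exact test, limma-voom, a replicate block, an added threshold of 1 on the absolute log2 fold change, leaving out each library in turn, and lists without genes shared between lists. Chosen after seeing the data were a restriction to protein-coding genes, a test against a fold of 1.5 with glmTreat, and lists without genes whose symbol starts with H2. Analyses ran in R 4.3.3 and Python 3.11.15.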

Results

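Gene expression was measured by RNA sequencing in 4 libraries of whole mouse testis, in 2 groups of 2. By the labels, every mouse had received LPS, and the groups differed in a knockdown of Spry1, a feedback inhibitor of receptor tyrosine kinase signalling, against a control hairpin. The series title sets this in the context of Dmrt1, a transcription factor of Sertoli and germ cells, and of NF-kB signalling. The count columns are headed LPS and NC, and they were assigned to the knockdown and the control by a reading of those names. If the headings instead mean LPS against no LPS, every difference given here belongs to that contrast. Libraries held 17612342 to 22451132 counts and 29393 to 30606 detected genes, and mitochondrial genes took 0.524% to 0.590% of the counts.

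Spry1, the targeted gene, was lower in the LPS columns, with 26 and 17 counts against 45 and 41 in the NC columns. Its level was 1.14 ± 0.26 CPM against 2.02 ± 0.03 CPM (SD, n = 2 per group), which is 0.567 of the NC level. Its counts had been seen when the columns were assigned, so they do not check that assignment independently. The log2 fold change was -0.82 with an SE of 0.28, and edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment gave an adjusted p of 0.0212. Spry1 (ENSMUSG00000037211.12) is a protein-coding gene on chromosome 3, from 37639947 to 37644598 in mm10, and it overlaps the gene model Gm42922, so its low counts are uncertain. The call was lost with DESeq2 (Benjamini-Hochberg adjusted p = 0.297), and in edgeR's test without LPS replicate 2 (log2 fold change -0.61, adjusted p = 0.183), without NC replicate 1 (-0.79, adjusted p = 0.0952) and without NC replicate 2 (-0.83, adjusted p = 0.0653). Over all alternatives its adjusted p, Benjamini-Hochberg in each tool including edgeR, ranged from 0.0150 to 0.297.

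Among the 10 largest rises, Acod1, which makes itaconate in activated macrophages, had 43 and 44 counts in the LPS columns and 0 in both NC libraries, at least 32.8-fold higher. Saa3, an acute-phase protein, was at 119 ± 3.65 CPM against 0.581 ± 0.694 CPM, and complement C3 was at 491 ± 83.8 CPM against 9.40 ± 1.73 CPM (SD, n = 2 per group). Klrb1, a lectin-like receptor gene, showed the opposite pattern, with 0 counts in both LPS libraries and 42 and 45 in the NC libraries, at least 25.6-fold lower. Erbb3, a receptor tyrosine kinase, fell from 25.8 ± 1.38 CPM to 0.988 ± 0.107 CPM.

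Of 20855 genes tested, 3169 were higher and 3394 lower in the LPS columns by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. With an absolute log2 fold change of at least 1 as well, 665 were higher and 567 lower. With library size as the only scaling, 4207 were higher and 2579 lower, so that 62% of calls were higher against 48.3% with TMM scaling. DESeq2 called 1370 higher and 1747 lower. The 2 libraries of each group lay apart from those of the other in 64.1% of genes, where chance gives 33.3%. Across the 20855 genes, which are not independent replicates, the log2 fold change had a Spearman rho of 0.138 with gene length, so that longer genes tended to be higher in the LPS columns.

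The other genes with the largest rises were the chemokine Cxcl13, the scavenger receptor Marco, the pattern-recognition lectin Clec4e, the protease inhibitor Serpina3n, and H2-Q1, H2-Q2 and H2-K2 of the MHC region. Cxcl13 had 159 and 191 counts against 1 and 2, a ratio of 132.1 with a counting interval of 44.8 to 643. Clec4e had 39 and 39 counts against 0 and 1, a ratio of 88.3 with a counting interval of 15.4 to 3531. Marco had a log2 fold change of 6.18 ± 0.20 (SE), H2-Q1 of 6.20 ± 0.38 and H2-Q2 of 5.22 ± 0.20. Serpina3n was at 44.0 ± 4.54 CPM against 1.38 ± 0.60 CPM. H2-K2, annotated as a transcribed pseudogene, had 61 and 78 counts against 0 and 3, a ratio of 52.4 with a counting interval of 17.6 to 257. The H2 and Serpina3 genes belong to families of near-identical copies and are uncertain for that reason. Fitted values against so few NC counts moved with single libraries. Over the alternatives, with the lowest value without NC replicate 1 and the highest without NC replicate 2, Saa3 ranged from 6.79 to 10.25, H2-Q1 from 5.21 to 10.20, H2-K2 from 4.61 to 9.20, Clec4e from 5.24 to 8.37 and Marco from 5.56 to 7.21 on the log2 scale.

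Among the other genes with the largest falls, Itpr3os, an antisense gene that overlaps Itpr3, fell by 6.35 on the log2 scale with an SE of 0.16. The glutamate receptor gene Grm4 fell by 4.92 ± 0.34, Prol1 fell by 4.74 ± 0.15 and the protocadherin gene Pcdh9 fell by 3.83 ± 0.39. Mettl7b, which overlaps Itga7, fell by 3.70 ± 0.26. Of the near-identical pair on chromosome 14, Plac9a fell by 3.63 ± 0.19 and Plac9b fell by 3.18 ± 0.09. Cyp21a1, a steroid 21-hydroxylase gene that overlaps Tnxa, fell by 3.18 ± 0.25.

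**Figure D1:**
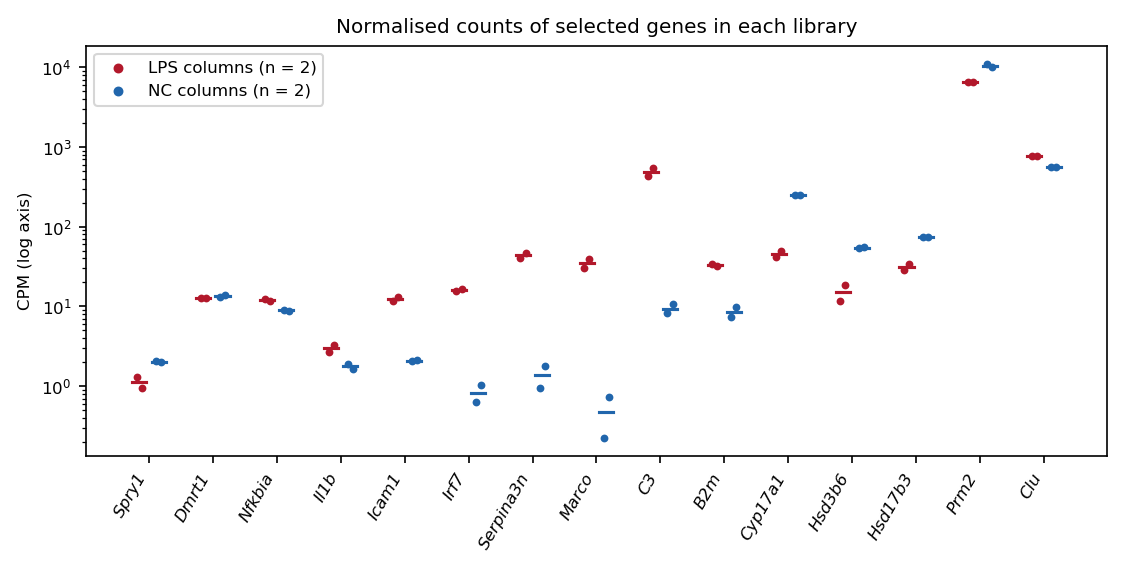
Normalised counts (CPM, log axis) of 15 genes in each library, with LPS columns in red and NC columns in blue. Each point is a library and each bar the mean of 2 libraries, and C3, for example, stood at 491 CPM in the LPS columns against 9.40 CPM in the NC columns.

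Genes of the NF-kB pathway were mostly higher. Of 24 tested members, 17 rose, 0 fell and 7 were not called, and 18 rose and 1 fell when adjusted over the list alone. The adhesion molecule gene Icam1 rose by 2.55 ± 0.16 (log2, SE), Tnip1, whose product binds the NF-kB inhibitor A20, by 1.11 ± 0.07 and Vcam1 by 0.93 ± 0.08. Nfkbia, which encodes the inhibitor IkB-alpha, rose by 0.41 ± 0.12 (edgeR, Benjamini-Hochberg adjusted p = 0.00526), a call lost with DESeq2 (adjusted p = 0.131, range over alternatives 0.00221 to 0.131). Camera called the NF-kB list higher with Benjamini-Hochberg adjustment (adjusted p = 1.63e-09), with adjusted p = 0.0899 with an estimated correlation. Dmrt1 was not called, with a log2 fold change of -0.07 ± 0.11 (edgeR, Benjamini-Hochberg adjusted p = 0.667) and 12.8 ± 0.03 CPM against 13.4 ± 0.56 CPM.

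Chemokine genes rose in 12 of 15 tested members, 1 fell and 2 were not called, and 12 rose and 2 fell when adjusted over the list alone. Cxcl9 rose by 3.32 ± 0.33 (3.94 without NC replicate 1) and Cxcl1, a neutrophil attractant, by 3.33 ± 0.41. Ccl2, a monocyte attractant, had 24 and 14 counts against 0 and 1, a ratio of 43.0 with a counting interval of 7.27 to 1743, and its fitted log2 fold change was 4.21 without NC replicate 1 and 7.33 without NC replicate 2. Cxcl10 had 7 and 11 counts against 1 and 0 and was too low to be tested. The member that fell was Ccl24, with 0 counts in both LPS libraries and 19 and 12 in the NC libraries. Camera called the chemokine list higher with Benjamini-Hochberg adjustment (adjusted p = 3.5e-08), with adjusted p = 0.0945 with an estimated correlation.

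Of 11 tested inflammatory cytokine genes, 5 rose, 1 fell and 5 were not called, with the same counts of 5 and 1 when adjusted over the list alone. Tnf had 14 and 13 counts against 0 in both NC libraries, at least 10.2-fold higher. Csf1 rose by 0.89 ± 0.16, Hmgb1 rose, Il11 fell, and the interleukin-1 receptor antagonist gene Il1rn had 13 and 14 counts against 0 and 3, a ratio of 10.2 with a counting interval of 3.14 to 52.5. The fitted log2 fold change of Il1rn was 2.26 without NC replicate 1 and 6.85 without NC replicate 2. Il1b, which overlaps the antisense gene Il1bos, rose by 0.74 ± 0.23 (edgeR, Benjamini-Hochberg adjusted p = 0.0119). Its call was lost with DESeq2 (adjusted p = 0.221), and in edgeR without LPS replicate 2 (adjusted p = 0.121) and without NC replicate 2 (adjusted p = 0.0782), over a range of 0.00686 to 0.221. Il6 had 2 and 0 counts against 0 in both NC libraries, at which depth no difference could be detected. The list did not pass camera with Benjamini-Hochberg adjustment (adjusted p = 0.0733, and adjusted p = 0.265 with an estimated correlation), and fry gave an adjusted p of 0.0339.

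Among LPS sensing and TLR4 signalling genes, 6 of 22 tested members rose, 0 fell and 16 were not called, and 8 rose and 1 fell when adjusted over the list alone. Lbp, the LPS-binding protein gene, rose by 2.07 ± 0.11 and Tlr2 by 2.22 ± 0.46. The co-receptor gene Cd14 rose from 0.375 ± 0.048 CPM to 2.18 ± 0.72 CPM (SD, n = 2 per group). The Tlr2 call was lost in edgeR's test without LPS replicate 2 (log2 fold change 1.63, Benjamini-Hochberg adjusted p = 0.0564, the highest over its alternatives, with 3.34e-06 the lowest). Camera called the LPS sensing list higher with Benjamini-Hochberg adjustment (adjusted p = 7e-04), with adjusted p = 0.188 with an estimated correlation.

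Interferon-stimulated genes rose in 29 of 35 tested members, 3 fell and 3 were not called, and 29 rose and 4 fell when adjusted over the list alone. The median log2 fold change was 1.89. Irf7, a transcription factor of the interferon response, rose by 4.28 ± 0.18 and the GTPase gene Gbp3 by 2.73 ± 0.13. The members that fell were Mx1 (log2 fold change -0.90 ± 0.26), Isg20 (-0.36 ± 0.08) and Dhx58 (-0.25 ± 0.08). Camera called the interferon list higher with Benjamini-Hochberg adjustment (adjusted p = 2.01e-28), with adjusted p = 0.0757 with an estimated correlation.

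Acute-phase and endotoxin-response genes rose in 16 of 21 tested members, 1 fell and 4 were not called, and 17 rose and 1 fell when adjusted over the list alone. Besides Saa3 and Serpina3n, the copper carrier gene Cp rose by 2.83 ± 0.10. The member that fell was Thbs1 (log2 fold change -0.91 ± 0.22). Camera called the acute-phase list higher with Benjamini-Hochberg adjustment (adjusted p = 4.2e-49), with adjusted p = 0.0757 with an estimated correlation.

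Complement genes rose in 9 of 16 tested members, 0 fell and 7 were not called, and 10 rose and 0 fell when adjusted over the list alone. Beside C3, the alternative pathway gene Cfb rose by 3.14 ± 0.12 and the classical pathway protease gene C1s1 by 2.26 ± 0.09. Camera called the complement list higher with Benjamini-Hochberg adjustment (adjusted p = 4.21e-32), with adjusted p = 0.0899 with an estimated correlation. MHC antigen presentation genes rose in 15 of 22 tested members, 3 fell and 4 were not called, with the same counts of 15 and 3 when adjusted over the list alone. The class I genes H2-D1 and H2-Q4 rose by 2.74 ± 0.07 and 3.67 ± 0.14, and B2m, the light chain of class I molecules, by 1.98 ± 0.10. The 3 that fell were the class II genes H2-Ab1 (log2 fold change -0.54 ± 0.13) and H2-Eb1 (-0.75 ± 0.27) and the class I regulator Nlrc5 (-0.62 ± 0.14). Camera called the MHC list higher with Benjamini-Hochberg adjustment (adjusted p = 3.94e-25), with adjusted p = 0.0899 with an estimated correlation.

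Markers of immune cells moved in both directions beside these groups. Of 20 tested macrophage and monocyte markers, 9 rose, 6 fell and 5 were not called, and 11 rose and 6 fell when adjusted over the list alone. Itgam rose by 2.68 ± 0.18, Adgre1 by 1.97 ± 0.16 and Mpeg1 by 1.40 ± 0.12, while Mrc1 fell by 0.67 ± 0.10 and Csf1r fell by 0.74 ± 0.14. Camera called the macrophage list higher with Benjamini-Hochberg adjustment (adjusted p = 0.00174), with adjusted p = 0.242 with an estimated correlation. Of 6 tested neutrophil markers, 2 rose, 0 fell and 4 were not called, and 3 rose and 1 fell when adjusted over the list alone. S100a9 had 35 and 32 counts against 0 in both NC libraries, at least 25.3-fold higher, and Mpo had a log2 fold change of 1.14 ± 0.36. The neutrophil list did not pass camera with Benjamini-Hochberg adjustment (adjusted p = 0.134, and adjusted p = 0.298 with an estimated correlation), and fry gave an adjusted p of 0.00653. It passed camera with no filter on low counts (Benjamini-Hochberg adjusted p = 0.0426, range over alternatives 0.00653 to 0.298). The Mpo call was lost with DESeq2 (adjusted p = 0.259, range over alternatives 0.00841 to 0.259) and, in edgeR with Benjamini-Hochberg adjustment, without LPS replicate 1 (adjusted p = 0.0710), LPS replicate 2 (adjusted p = 0.0562) or NC replicate 1 (adjusted p = 0.142).

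Of 11 tested lymphocyte and NK cell markers, 1 rose, 3 fell and 7 were not called, with the same counts of 1 and 3 when adjusted over the list alone. Ptprc, the pan-leukocyte antigen gene, rose by 1.70 ± 0.23, while the immunoglobulin gene Ighm fell by 3.03 ± 0.51 and the T cell gene Cd8b1 fell by 1.31 ± 0.33. The remaining member that fell was Cd2. The Cd8b1 call was lost with DESeq2 (adjusted p = 0.112, range over alternatives 0.000291 to 0.112) and, in edgeR with Benjamini-Hochberg adjustment, without LPS replicate 1 (adjusted p = 0.0681) or NC replicate 2 (adjusted p = 0.0633). The list did not pass camera with Benjamini-Hochberg adjustment (adjusted p = 0.695, and adjusted p = 0.805 with an estimated correlation). Of 6 tested erythroid genes, 0 rose, 3 fell and 3 were not called, with the same counts of 0 and 3 when adjusted over the list alone. Among those not called were the globin genes Hba-a1 and Hbb-bs, with log2 fold changes of -0.328 ± 0.239 and -0.511 ± 0.265. Alas2, the first enzyme of erythroid haem synthesis, fell by 0.79 ± 0.13, Bpgm fell by 0.25 ± 0.06, and Slc4a1 fell from 1.40 ± 0.63 CPM to 0.702 ± 0.275 CPM (SD, n = 2 per group). The erythroid list did not pass camera with Benjamini-Hochberg adjustment (adjusted p = 0.105, and adjusted p = 0.526 with an estimated correlation), but passed as lower without NC replicate 1 (adjusted p = 0.0310, range over alternatives 0.0310 to 0.526). The Slc4a1 call was lost with DESeq2 (Benjamini-Hochberg adjusted p = 0.346), with limma-voom (adjusted p = 0.0565), with library size as the only scaling (edgeR, adjusted p = 0.0587), without LPS replicate 1 (edgeR, Benjamini-Hochberg adjusted p = 0.284) and without NC replicate 2 (adjusted p = 0.575), over a range of 0.00622 to 0.575, and that of Bpgm without NC replicate 2 (adjusted p = 0.0603).

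**Figure D2:**
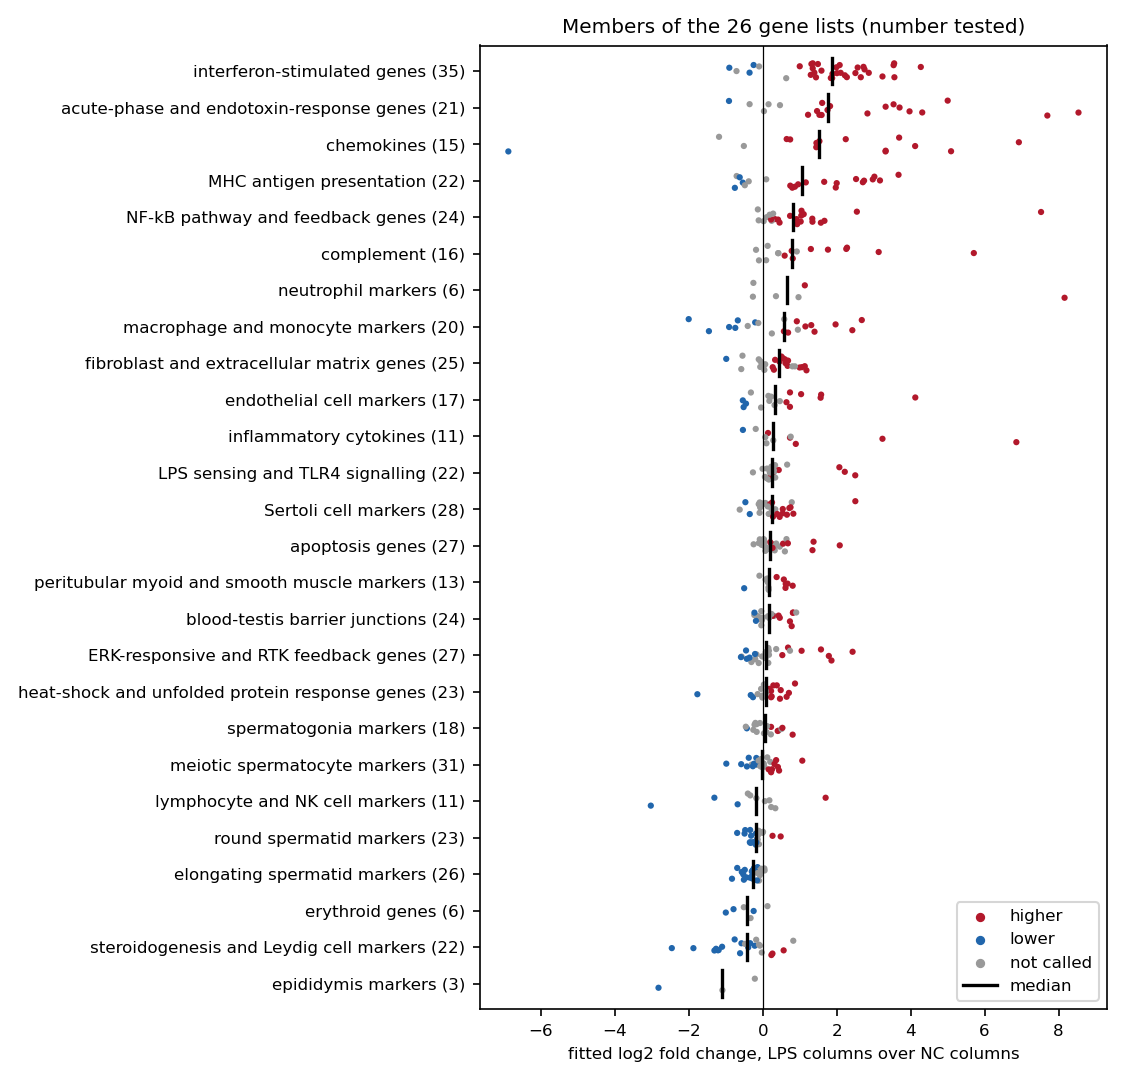
Fitted log2 fold changes, LPS columns over NC columns, of the tested members of the 26 gene lists, ordered by median. Red points were called higher, blue points lower and grey points were not called, the black bars are medians, and the interferon-stimulated genes have a median of 1.89. Points of genes at 0 in a group depend on the prior count of the fit.

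Genes of steroid synthesis in Leydig cells, the androgen-producing cells of the testis, were mostly lower. Of 22 tested steroidogenesis and Leydig cell markers, 13 fell, 3 rose and 6 were not called, and 13 fell and 4 rose when adjusted over the list alone. Cyp17a1 fell by 2.46 ± 0.07 (log2, SE), to 0.182 of the NC level, Hsd3b6 fell by 1.87 ± 0.10 and Hsd17b3, which makes testosterone, fell by 1.26 ± 0.07. The 3 that rose were Nr5a1, by 0.57 ± 0.09, Cyp11a1, by 0.26 ± 0.07, and Por, by 0.23 ± 0.09. The Leydig cell hormone gene Insl3 was not called, at -0.07 ± 0.06. Camera called the Leydig list lower with Benjamini-Hochberg adjustment (adjusted p = 4.16e-17), with adjusted p = 0.242 with an estimated correlation. Of 3 tested epididymis markers, too few for a test of the list, 1 fell, 0 rose and 2 were not called, and 2 fell and 0 rose when adjusted over the list alone. Sult1e1, an oestrogen sulfotransferase gene also expressed in Leydig cells, fell by 2.82 ± 0.10, and Cuzd1 and Wfdc15a were at -1.09 ± 0.44 and -0.21 ± 0.17.

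Markers of late germ cells fell more often than they rose. Of 26 tested elongating spermatid markers, 18 fell, 0 rose and 8 were not called, and 20 fell and 0 rose when adjusted over the list alone. The protamine genes Prm2 and Prm1, whose products package sperm DNA, had log2 fold changes of -0.69 ± 0.05 and -0.48 ± 0.05, and Spata3 fell by 0.53 ± 0.05. Camera called the elongating spermatid list lower with Benjamini-Hochberg adjustment (adjusted p = 2.83e-09), with adjusted p = 0.0899 with an estimated correlation. Of 23 tested round spermatid markers, 13 fell, 2 rose and 8 were not called, and 15 fell and 2 rose when adjusted over the list alone. Spag6 fell by 0.69 ± 0.06, the sperm calcium channel gene Catsper4 fell by 0.49 ± 0.07, and the members that rose were Cst13, by 0.49 ± 0.07, and Spaca1. The round spermatid list was lower by camera with Benjamini-Hochberg adjustment (adjusted p = 0.000774), with adjusted p = 0.298 with an estimated correlation.

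Earlier germ cell markers moved in both directions. Of 31 tested meiotic spermatocyte markers, 9 rose, 8 fell and 14 were not called, and 9 rose and 9 fell when adjusted over the list alone. Prdm9, which marks recombination sites, rose by 1.07 ± 0.12, while Meiob fell by 0.98 ± 0.11 and Rec8, a meiotic cohesin gene, fell by 0.43 ± 0.07. The list did not pass camera with Benjamini-Hochberg adjustment (adjusted p = 0.998, and adjusted p = 0.998 with an estimated correlation). Of 18 tested spermatogonia markers, 4 rose, 1 fell and 13 were not called, with the same counts of 4 and 1 when adjusted over the list alone. Stra8, a gene of meiotic entry, rose by 0.81 ± 0.08 and Kit by 0.41 ± 0.11, beside Zbtb16 and Id4, and Etv5 fell by 0.43 ± 0.13. The spermatogonia list did not pass camera with Benjamini-Hochberg adjustment (adjusted p = 0.327, and adjusted p = 0.526 with an estimated correlation). The Kit call was lost with DESeq2 (adjusted p = 0.0867) and, in edgeR with Benjamini-Hochberg adjustment, without NC replicate 1 (adjusted p = 0.0615), and the Etv5 call with DESeq2 (adjusted p = 0.202) and without LPS replicate 2 (adjusted p = 0.107) or NC replicate 1 (adjusted p = 0.0822).

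Somatic cell markers of the tubule and its wall rose more often than they fell. Of 28 tested Sertoli cell markers, 13 rose, 2 fell and 13 were not called, and 15 rose and 2 fell when adjusted over the list alone. Cst9 rose by 2.51 ± 0.12, the protease gene Ctsl by 0.54 ± 0.05 and Clu by 0.46 ± 0.05, while Amhr2 and Trf fell. Camera called the Sertoli list higher with Benjamini-Hochberg adjustment (adjusted p = 3.57e-05), with adjusted p = 0.242 with an estimated correlation. Of 24 tested genes of the blood-testis barrier junctions, 8 rose, 2 fell and 14 were not called, with the same counts of 8 and 2 when adjusted over the list alone. The cadherin gene Cdh2 rose by 0.82 ± 0.06, F11r by 0.78 ± 0.12 and the cingulin gene Cgn by 0.43 ± 0.05, while Nectin3 fell. The junction list was higher by camera with Benjamini-Hochberg adjustment (adjusted p = 0.0349), with adjusted p = 0.242 with an estimated correlation, and its call was also lost without LPS replicate 2 (adjusted p = 0.0544) or NC replicate 2 (adjusted p = 0.0890).

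Of 13 tested peritubular myoid and smooth muscle markers, 6 rose, 1 fell and 6 were not called, and 7 rose and 1 fell when adjusted over the list alone. Myh11 and Acta2, both of the contractile apparatus, rose by 0.57 ± 0.05 and 0.62 ± 0.07, and Actg2 fell by 0.50 ± 0.05. Camera called the peritubular list higher with Benjamini-Hochberg adjustment (adjusted p = 0.00724), with adjusted p = 0.242 with an estimated correlation. Of 25 tested fibroblast and extracellular matrix genes, 14 rose, 1 fell and 10 were not called, and 15 rose and 3 fell when adjusted over the list alone. The basement membrane collagen genes Col4a2 and Col4a1, which overlap at their ends, rose by 1.14 ± 0.08 and 1.06 ± 0.08, and Col3a1 by 1.18 ± 0.08, and the member that fell was Postn. The matrix list was higher by camera with Benjamini-Hochberg adjustment (adjusted p = 6.25e-07), with adjusted p = 0.265 with an estimated correlation. Of 17 tested endothelial cell markers, 7 rose, 3 fell and 7 were not called, with the same counts of 7 and 3 when adjusted over the list alone. Ly6c1, Mmrn2 and Tek rose by 4.13 ± 0.46, 1.58 ± 0.32 and 1.04 ± 0.23, and Vwf, Flt1 and Sele fell. Without NC replicate 1 the log2 fold change was 3.43 for Ly6c1 and 2.29 for Mmrn2, and without NC replicate 2 it was 5.39 for Ly6c1. The endothelial list did not pass camera with Benjamini-Hochberg adjustment (adjusted p = 0.104, and adjusted p = 0.265 with an estimated correlation), but passed as higher without NC replicate 1 (adjusted p = 0.0348, range over alternatives 0.0348 to 0.412).

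Spry1 acts on signalling that leads to ERK, and the genes that respond to it moved in both directions. Of 27 tested ERK-responsive and RTK feedback genes, 7 rose, 5 fell and 15 were not called, with the same counts of 7 and 5 when adjusted over the list alone. The immediate early genes Junb, Egr1 and Fos rose by 1.86 ± 0.12, 1.58 ± 0.16 and 2.43 ± 0.40, and those that fell were Spred3, Etv5, Sh2b3, Fosl1 and Il17rd. Without NC replicate 2 the log2 fold change of Fos was 3.16. The Spry1 paralogues Spry2 and Spry4 were not called, at 0.74 ± 0.39 and 0.10 ± 0.30. The list did not pass camera with Benjamini-Hochberg adjustment (adjusted p = 0.104, and adjusted p = 0.265 with an estimated correlation), and fry gave an adjusted p of 0.00653.

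Of 27 tested apoptosis genes, 8 rose, 0 fell and 19 were not called, and 7 rose and 0 fell when adjusted over the list alone. The TNF receptor gene Tnfrsf1b rose by 2.08 ± 0.37, Diablo by 0.20 ± 0.05 and the survival gene Mcl1 by 0.27 ± 0.07. Camera called the apoptosis list higher with Benjamini-Hochberg adjustment (adjusted p = 0.0442), with adjusted p = 0.242 with an estimated correlation, and its call was also lost with library size as the only scaling (adjusted p = 0.0614), with a stricter filter (adjusted p = 0.165), and without LPS replicate 2 (adjusted p = 0.0897) or NC replicate 1 (adjusted p = 0.0613). The Mcl1 call was lost with DESeq2 (adjusted p = 0.0694) and, in edgeR with Benjamini-Hochberg adjustment, without LPS replicate 2 (adjusted p = 0.0705) or NC replicate 1 (adjusted p = 0.115). Of 23 tested heat-shock and unfolded protein response genes, 11 rose, 3 fell and 9 were not called, with the same counts of 11 and 3 when adjusted over the list alone. The chaperone genes Hspa1b, Pdia4 and Hspa8 rose by 0.71 ± 0.10, 0.47 ± 0.06 and 0.38 ± 0.05, and the log2 fold changes of those that fell were -1.77 ± 0.31 for Chac1, -0.32 ± 0.07 for Herpud1 and -0.26 ± 0.07 for Dnajb9. The heat-shock and unfolded protein response list was higher by camera with Benjamini-Hochberg adjustment (adjusted p = 0.0135), with adjusted p = 0.265 with an estimated correlation. Its median log2 fold change was only 0.09.

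In all, 14 of the 25 tested lists were higher and 3 lower by camera with the preset correlation. The shifts differed widely in size. Against a median log2 fold change of 1.89 for the interferon list, medians were 0.16 for the junction and peritubular lists. They were 0.20 for the apoptosis, 0.25 for the Sertoli, -0.17 for the round spermatid and -0.25 for the elongating spermatid list. With an estimated correlation camera called 0 lists after Benjamini-Hochberg adjustment, the smallest adjusted p being 0.0757, and 7 lists had an unadjusted p under 0.05. That form of the test rests on 2 residual degrees of freedom and has little power here. The estimated correlation of the interferon list was 0.00112, below the preset 0.01, so a larger correlation did not take its call. Other called lists had estimates far above the preset. These were 0.485 for the Leydig, 0.353 for the matrix, 0.219 for the round spermatid, 0.181 for the complement and 0.109 for the Sertoli list. For such lists the p with the preset may be too small, and correlation and low power cannot be told apart as reasons for the lost call. Fry, which tests whether the genes of a list move on balance in a single direction, called 17 lists higher and 3 lower.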

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

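Chosen only after the result was seen were the tests with glmTreat, with protein-coding genes and with lists without H2 genes. Against 3169 genes higher and 3394 lower, DESeq2 called 1370 and 1747, of which 3116 in total were shared with the calls of edgeR. A minimum absolute log2 fold change of 1 left 665 and 567, and glmTreat against a fold of 1.5 left 462 and 389. These last counts follow from the stricter thresholds, and for DESeq2 the cause was not tested. The other settings stayed within 1.5 times of both counts, and 3210 of the 6563 calls were kept in all 4 fits without a library, in which the lone library was assumed to vary like the other group. Lists called fell from 14 higher and 3 lower to 0 and 0 with an estimated correlation, where 2 residual degrees of freedom gave little power. Otherwise both counts of lists stayed within 1.5 times. The endothelial and erythroid lists passed only without NC replicate 1, and the neutrophil list only with no filter on low counts or with fry. Spry1 kept its direction throughout, with a log2 fold change of -0.83 in DESeq2 (adjusted p = 0.297, the highest of a range from 0.0150) and of -1.08 to -0.61 in edgeR with a library left out, and the cause was not tested. Of 99 single genes followed across the settings, 11 lost their call under at least 1 setting and 0 changed direction. DESeq2 gave Tnf no adjusted p, and it is not among the lost calls. With the stricter filter only 80 of the 99 were tested, and each fit without an LPS library also left a gene out. Genes left out are not counted as lost calls. The meiotic list, never called, turned to higher by camera with Benjamini-Hochberg adjustment with upper-quartile factors (adjusted p = 0.991), library size only (adjusted p = 0.674), a stricter filter (adjusted p = 0.937) and without LPS replicate 2 (adjusted p = 0.544, in a range of 0.499 to 0.965 over the libraries left out). The lymphocyte list turned to higher with a stricter filter (adjusted p = 0.604, in a range of 0.266 to 0.899), and the cause was not tested. The replicate numbers are shared between groups, and deviations of same-numbered libraries had a correlation of 0.0123 across 12301 genes, which gives no sign of pairing. With a replicate block edgeR called 3376 genes higher and 3594 lower, 14 lists higher and 3 lower, and Spry1 at -0.82 (adjusted p = 0.0150). Depth limited genes of few counts, such as Il6 and Cxcl10, which were not tested.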

Other observations

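All of the tests of explanations in this part were chosen only after the results were seen, as were the bounds used to read them, and the genes named only here were chosen after their values were seen.

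Some of the genes with large changes outside the fixed lists lay in clusters on the chromosomes, while most did not. Outside the lists by symbol, 280 genes changed at least 4-fold, 164 higher and 116 lower in the LPS columns. Some of them overlap list members, such as Gm16567 with C1s1 and Gm11131 with H2-Q4, so reads of list genes may be counted among them. In windows of 5 Mb, 16 windows held at least 4 such genes, against a mean of 3.8 and a highest value of 11 over 10000 shuffles (permutation p = 1e-04, the smallest the shuffles can give). In 5 windows all such genes were higher, in 1 window, on chromosome 1, all 4 were lower, and 10 windows held both. Several windows hold families of near-identical genes, and on chromosome 14 a window of 36 tested genes had 9 changed unnamed genes, 8 higher and 1 lower. In the MHC window of chromosome 17, 9 of 100 tested genes changed and all 9 were higher, among them H2-Q5, H2-Q10 and H2-T10. Some genes with the largest falls also lay in such windows. On chromosome 17, Grm4 and Itpr3os lay in the window from 25 Mb (1 higher, 3 lower). Cyp21a1 lay with H2-K2 in the window from 30 Mb (3 higher, 1 lower), next to the MHC window. On chromosome 10, Erbb3 and Mettl7b shared a window (1 higher, 3 lower). Whether the genes of a window changed for a shared reason was not tested. On chromosome 5, the 5 changed genes of a window of 66 were all higher and included the interferon-inducible GTPase genes Gbp4, Gbp6, Gbp9 and Gbp10. On chromosome 2, 8 zinc-finger or unnamed genes between 175129493 and 177012787 were all higher, with summed counts of 213 and 194 in the LPS libraries against 8 and 13 in the NC libraries.

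The NF-kB, chemokine, LPS sensing, interferon, acute-phase, complement and MHC lists were higher in the LPS columns by camera with the preset correlation. With an estimated correlation, which leaves little power at 2 residual degrees of freedom, none passed (smallest Benjamini-Hochberg adjusted p = 0.0757). The inflammatory cytokine and neutrophil lists passed camera in neither way. A hypothesis is that the column groups differ in LPS exposure and not, or not only, in the hairpin. Of 21 tested acute-phase and endotoxin-response genes, 3 were at 10 CPM or more in the NC columns, 9 were under 1 CPM and 9 lay between. Of those 3, Lcn2 had 1240 and 1278 counts in the NC libraries and was called higher. The others, Mt1 and Mt2, were not called, with log2 fold changes of 0.03 and 0.16. A difference in LPS exposure would change them only if they respond to LPS in testis, which these data do not show, so they do not decide. Among those under 1 CPM were Acod1, at 0 in both NC libraries, and Saa3, with 2 and 22 counts. Levels of this kind may come from mice without LPS or from control mice with a weak response to it, and these cannot be told apart because no library outside the 2 column groups gives a reference. A larger share of leukocytes in the LPS columns, of all types alike, is argued against as the whole cause by markers that fell. Of the called macrophage and monocyte markers, 6 were lower (Mrc1, Cx3cr1, Csf1r, Aif1, Pf4 and Cd163) and 9 higher. Aif1 had 5618 and 5121 counts against 7025 and 6961, far above the others of the 6, so it may not mark leukocytes here. Of the lymphocyte and NK cell markers, 1 rose, the pan-leukocyte gene Ptprc, by 1.70 ± 0.23, and 3 fell. An influx of a single leukocyte type stays open, and so does a larger share of leukocytes together with lower levels of the fallen markers within them. The knockdown of Spry1 itself stays open as well, as the explanation that the labels name.

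Near all-or-none genes were found in both directions. With at least 20 summed counts in the other group, 16 genes were at 0 in both NC libraries and 15 at 0 in both LPS libraries, and 26 of these are in no fixed list by symbol. Among the 26, Mir6978, with 14 and 18 counts in the LPS libraries, lies within the list member C3, so its reads may be those of C3. A hypothesis is sequence or copy-number differences between the mice of the 2 column groups, which may exist although the labels give the strain C57BL/6J for all. Of the 3 parent genes of 4 ribosomal-protein pseudogenes changed at least 4-fold, 2 (Rps2 and Rps26) were called in the opposite direction, too few to decide. Rps2 rose by 1.54 on the log2 scale while Rps2-ps10 had 9 and 8 counts against 1873 and 1632. Rps2-ps13 had 9 and 10 against 60 and 61, far less than the rise of Rps2. The summed CPM of parent and pseudogene did not balance either. Its log2 ratio was -0.58 for Rps2 with Rps2-ps10 and -0.691 for Rps26 with Rps26-ps1. For Rps2 with Rps2-ps13 it was 1.39, but that sum leaves out the NC counts of Rps2-ps10, so it does not give the balance of Rps2 with both pseudogenes. Reads moving to the 8 risen zinc-finger or unnamed genes of chromosome 2 from the other counted copies of their window would lower those copies. The 83 zinc-finger and unnamed genes other than the 8 were not lower in sum, with 17.9 and 16.5 CPM against 13.5 and 11.8 CPM. This argues against a move of reads from the 83 as a set. They were picked by symbol, tested or not, and their likeness in sequence to the 8 was not checked. A loss from a few true copies among them stays open. The summed CPM of all 91, which includes the 8, was 2.12 times as high in the LPS columns. Reads left uncounted, or placed on copies outside the window, would not show in these sums and stay open. Differences in mapping of near-identical copies and a response to treatment were not separated for these or the remaining genes.

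Steroidogenic and spermatid lists were lower in the LPS columns by camera with the preset correlation, calls lost with an estimated correlation (Benjamini-Hochberg adjusted p = 0.242 for the Leydig list, 0.298 for round and 0.0899 for elongating spermatids). That form of the test had little power at 2 residual degrees of freedom. The estimated correlation was also far above the preset for the Leydig list (0.485) and the round spermatid list (0.219). For the elongating spermatid list it was not (-0.0239). A smaller share of Leydig cells as the whole cause is argued against by the 3 members of the Leydig list that rose, of which Cyp11a1 is the most specific to these cells, and by Insl3 at -0.07 ± 0.06. A smaller share of spermatids alone is argued against for the steroidogenic list, since it would raise the markers of other cells and 13 of 22 members of the Leydig list fell. For the spermatid lists it stays open: it would raise Sertoli and meiotic markers alike, and their medians differed by 0.265 on the log2 scale (permutation p = 0.02, two-sided, 100000 resamples of genes, which are not independent replicates), but 8 of 31 meiotic members fell while 9 rose, and members of the Sertoli list also went both ways, so the medians do not decide. A mixture of lower expression within Leydig cells and a change in several cell shares may account for the pattern and was not tested.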
